A study of uncultured soil microorganism with 16 samples.

How the data were processed

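Water from 16 outdoor, flow-through mesocosms was analysed with a functional gene microarray (GeoChip), which carries DNA probes for microbial genes of element cycling. Per the labels, the mesocosms were 1.9 m in diameter and 1 m deep with a retention time of about 2.5 months, 400 to 500 ml of water was used for the arrays, and 500 ng of community DNA was labelled with Cy3 by random priming. The labels cross 2 temperatures with 2 nutrient levels, giving a control, a warming, a nutrient enrichment and a combined warming and nutrients group of 4 mesocosms each, with warmed mesocosms kept 4 to 5 °C above ambient. One array was given for each mesocosm, so the p-values measure the spread between mesocosms, with sampling, labelling and array error inside it.

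The deposited values are linear Cy3 spot intensities, as judged from the values themselves. Each array has 50775 gene probes in 370 gene families, with a gene name, organism, category and lineage for each probe per the file headers. Spots without a value are blank. The scanner, the background correction, any scaling and the rule that left spots blank are not given in the sources used here, and neither a background signal nor a detection score was given beside the intensity. Median deposited intensities ranged from 1107 to 45319 between arrays, so each array is on a scale of its own. The main results compare values scaled between arrays. Results given without scaling carry these differences in array brightness, so their signs cannot tell whether genes changed. Spots with a value numbered 17188 to 31520 per array; this number differs between arrays within every group and is the depth limit of the data, because a blank gives only an upper bound. For arrays, the number of mesocosms limits the precision. Undetected spots could not be taken as measured, since they are blank.

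Invalid values were set to blank: 4 negative intensities on the array of nutrient enrichment replicate 3, and 262 intensities of control replicate 2 that were below the array's highest value divided by 1400, or, on that array only, more than 3.5 log2 units under the probe's median over at least 8 other arrays. The 212 of them that could be compared lay a median of 29.6-fold below the level of the same probes elsewhere, which partly follows from the rule that chose them. Their scale is unexplained in the sources used here. The log2 intensities were scaled by quantile normalization, with the mapping made on the 10972 probes that had a value on all 16 arrays and interpolated to the rest, and centred on the median of those probes, so 0 is that median. Blanks and values below the highest of the arrays' lowest values (log2 -3.19) were set to that common floor. A probe was kept when at least 3 of the 4 arrays of a group had a value, which left 28962 probes. The signal of a gene family was the mean over its kept probes, for the 304 families with at least 3 of them. A change of a family or probe is therefore on a floored log2 scale and understates changes of dim probes.

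Families and probes were tested with limma (version 3.58.1, R 4.3.3) in 1 model of all 16 arrays with a mean per group, with Benjamini-Hochberg adjustment over all families or probes of a comparison and a threshold of 0.05. The 6 comparisons were each treatment against control, the effect of warming averaged over both nutrient levels, the effect of enrichment averaged over both temperatures, and the interaction. Changes are treated minus control, or higher minus lower level of the factor. Intervals are 95% intervals of limma's moderated estimate. Community composition was tested on linear signals with blanks at 0 by permutational analysis of variance of Bray-Curtis dissimilarities (vegan 2.7.1, 9999 permutations). The number of spots with a value, the Shannon index and the shares of gene categories were compared with exact two-sided permutation tests over the 70 arrangements of 4 against 4 mesocosms, whose smallest p is 0.0286. A total of 26 gene lists were fixed before the data were examined. The 13 with at least 3 measured families were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists of nitrogen fixation, nitrification, ammonification and assimilation, anammox, methane production, methane oxidation, DMSP degradation and fungal forms had fewer members measured, and 5 lists (heat and cold shock, oxidative stress, phosphate and nitrogen limitation, antibiotic resistance, phage and virus functions) had none. The 40 categories of the annotation with at least 3 families and the 21 phyla with at least 20 kept probes were tested in the same way, chosen after the data were seen.

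The rule for named genes, set before the data were examined, was up to 6 families with the largest positive and 6 with the largest negative change past the threshold, 3 probes each way, and members of any list with a call. Where no family passed, the 5 with the smallest p are named as not passing. In every comparison 28 core families of nitrogen, carbon, phosphorus, sulfur and methane cycling are also reported; 27 of them were measured, and 1 name (aprA) matched no family name in the files exactly.

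On simulated data made from the residuals of these arrays, for warming against control, the family test of 304 families recovered 48.5% of changes of 0.5 log2 units, 87.5% of changes of 1 and 96.5% of changes of 1.5. The probe test over 28962 probes recovered 0.8% of changes of 1 log2 unit, 16.6% of changes of 2 and 74.9% of changes of 4. In each run many families or probes were raised at once, with the sizes mixed, which makes the adjusted threshold easier to pass. The recovered shares therefore overstate what the tests would find where only a few families or probes change, and lowered signals were not simulated. The shifts were also added in full to family means and to probe values at the floor. Blanks can hide part of a real change, which was not simulated, so the recovered shares are too high for this reason as well. With all members of the denitrification list shifted by 0.5, camera with the preset correlation called it in 20 of 20 runs. Other lists, camera with an estimated correlation and fry were not simulated.

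Groups were taken from the treatment labels. The sample code in the column heading of each file and the code in the description of the same sample agree in only 2 of 16 cases. Both kinds of code follow the labelled groups, each in its own way: the number in the headings differs between unwarmed and warmed mesocosms and their letters between nutrient levels, while the letters of the description codes differ between the 4 groups. Which code names the mesocosm is not given in the sources used here, so a regrouping that matches headings to description codes was run as an alternative. Alternatives were other scalings (75th percentile, total signal, none), an offset of 50, filters, blocks, array weights, other family summaries and each array left out in turn. Alternatives for blanks, invalid values, codes and arrays with few values were added after seeing the data. No slide or scan information was given, so no such batch was tested.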

Results

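The functional gene potential of the water was measured in 16 shallow-lake mesocosms, 4 each as control, under warming, under nutrient enrichment and under both treatments. The question was how warming and nutrients, alone and together, alter microbial genes of nutrient cycling. The array measures DNA, so values describe gene abundance and not activity. A gene family here is all probes of 1 gene, from many organisms, and its value is the mean normalised log2 signal of its kept probes.

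On average over all 16 mesocosms, genes of carbon cycling made up 43.8% ± 0.26 (SD, n = 16) of the probes with a value. Genes for the breakdown of organic contaminants made up 21.1% ± 0.31 and nitrogen genes 12.7% ± 0.27. Sulfur genes followed with 8.45% ± 0.083, metal homeostasis genes 7.23% ± 0.051 and phosphorus genes 4.30% ± 0.080. Bacterial probes accounted for 87.6% ± 0.32, eukaryotic probes for 8.79% ± 0.24 and archaeal probes for 2.48% ± 0.084. Proteobacteria held 39.1% ± 0.40 of the probes with a value, Actinobacteria 16.0% ± 0.95, Firmicutes 7.90% ± 0.42 and Cyanobacteria 2.30% ± 0.073. Among single families, amyA (alpha-amylase, which cleaves starch) had 2566 ± 409 probes with a value per array, ppx (exopolyphosphatase) 733 ± 119, chitinase 604 ± 107 and nifH (nitrogenase reductase) 601 ± 131. The number was 589 ± 117 for dsrA (dissimilatory sulfite reductase), 579 ± 88.8 for narG (nitrate reductase) and 118 ± 26.5 for mcrA (methyl-coenzyme M reductase, the last step of methane formation). These shares and counts depend on how many probes the array carries for each item, so they are not the makeup of the community. Of the probes placed for carbon cycling, 48.7% had a value on average, against 51.8% for nitrogen, 49.9% for sulfur and 51.4% for phosphorus. The figure was 51.7% for metal homeostasis and 59.1% for organic contaminants. Phyla differed more, with 74.6% for Actinobacteria, 56.1% for Proteobacteria, 41.8% for Cyanobacteria and 32.6% for Firmicutes. None of the 27 comparisons of category shares against control had an exact permutation p under 0.05 before adjustment (smallest 0.0571). Of the 48 comparisons of phyla 1 did, the Firmicutes share in the combined treatment, 7.46% ± 0.28 against 8.08% ± 0.34 in the controls (exact permutation p = 0.0286). Of the 84 comparisons of 28 larger subcategories 2 did, and of the 81 of core families 3 did. After Benjamini-Hochberg adjustment the smallest p was 0.579 for categories, 0.891 for phyla, 0.946 for subcategories and 0.771 for core families. A change in only a few shares could not pass this adjustment, because 0.0286 is the smallest p that 4 against 4 mesocosms can give.

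The number of probes with a value was 25995 ± 4948 (SD, n = 4) in the controls, 27485 ± 4087 under warming, 28078 ± 3006 under enrichment and 22841 ± 5052 under both. The differences from control were smaller than the spread between mesocosms, with exact two-sided permutation p of 0.571, 0.514 and 0.371. Without control replicate 3 the number was lower than in the controls under warming (difference -888) and under enrichment (-295). The Shannon index was 8.64 ± 0.12 in the controls, 8.64 ± 0.057 under warming, 8.66 ± 0.068 under enrichment and 8.55 ± 0.13 under both (exact permutation p = 0.943, 0.800 and 0.343). The Shannon difference turned negative for warming without control replicate 3 (-0.035) or 4 (-0.010) or warming replicate 1 (-0.007), 3 (-0.002) or 4 (-0.008), and for enrichment without control replicate 3 (-0.018) or, to just below 0, enrichment replicate 3. Under both treatments, the differences in probe number and Shannon index stayed negative with any array left out (-5531 to -1269 and -0.13 to -0.04). In whole-community composition, warming accounted for 7.30% of the variation in Bray-Curtis dissimilarity (permutation p = 0.194), nutrient enrichment for 7.08% (p = 0.258) and their interaction for 6.69% (p = 0.401), where 6.67% is what a factor with no effect takes on average. The mean dissimilarity was 0.481 ± 0.0345 (SD) over the 24 pairs of mesocosms of the same group and 0.485 ± 0.038 over the 96 pairs of different groups.

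**Figure D1:**
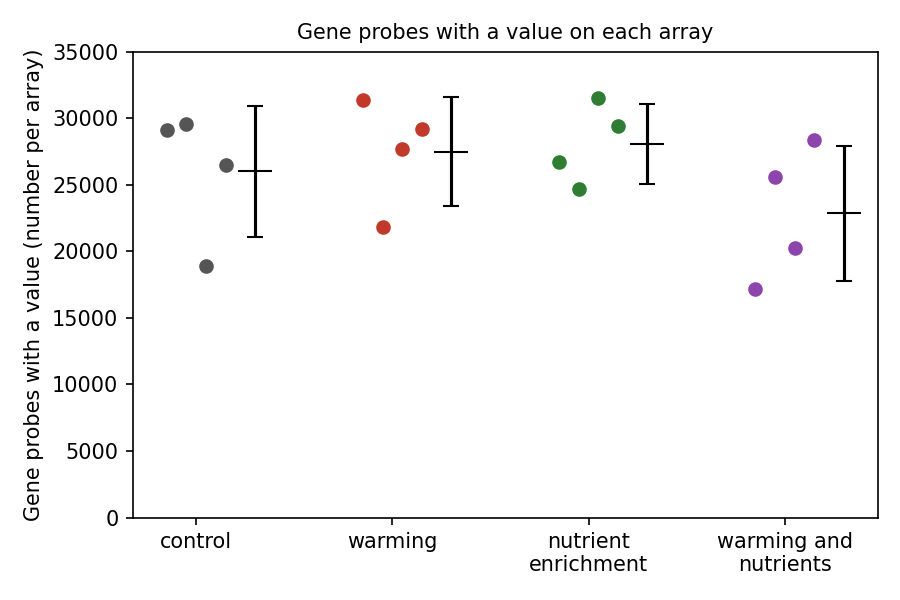
Number of gene probes with a value (y axis) on each of the 16 arrays, by treatment group (x axis); coloured points are mesocosms and the black bars show the mean ± SD of 4. The groups overlap, with arrays between 17188 and 31520, and the lowest array belongs to the combined treatment.

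The comparison of warmed with control mesocosms asks what warming does at the ambient nutrient level. None of the 304 gene families passed the limma test (11 had an unadjusted p under 0.05), and the 95% interval excluded a 2-fold change in either direction for 282 of them. Nitrogen-cycle families lay close to the controls: nifH differed by -0.09 ± 0.11 (SE) log2 units, amoA (ammonia monooxygenase) by -0.04 ± 0.15, narG by -0.09 ± 0.15, nirS and nirK (the nitrite reductases of denitrification) by -0.01 ± 0.14 and 0.03 ± 0.13, and nosZ (nitrous oxide reductase) by -0.08 ± 0.13. For methane genes the difference was -0.03 ± 0.17 in mcrA, -0.10 ± 0.12 in pmoA and 0.23 ± 0.16 in mmoX, the last 2 encoding methane monooxygenases. The differences were 0.04 ± 0.12 for rubisco, the carbon-fixing enzyme, 0.06 ± 0.12 for ppk (polyphosphate kinase), -0.05 ± 0.12 for dsrA, 0.04 ± 0.10 for amyA and 0.03 ± 0.11 for chitinase. All 27 core families lay between -0.19 and 0.23 and had intervals within a 2-fold change. Of them 14 lay above 0 with quantile, 17 with 75th percentile and 26 with total-signal scaling. All 27 lay below 0 without scaling, where array brightness enters and control replicate 2 has the highest median intensity (45319). These unscaled signs therefore cannot tell whether genes changed. The smallest p belonged to a marker of green plants and green algae, the cytochrome oxidase gene cox1 of Viridiplantae (7 probes). It was at -2.37 ± 0.15 (SD) under warming and -1.47 ± 0.62 in the controls, a difference of -0.90 ± 0.23 (SE) that did not pass (limma adjusted p = 0.382). It was followed, also not passing, by cmuA (annotated to chlorinated solvents, -0.51 ± 0.19), hsp90 of choanoflagellates (0.61 ± 0.25), axe (acetylxylan esterase, 0.31 ± 0.13) and the elongation factor gene of jakobids (0.82 ± 0.35), each with an adjusted p of 1.00. Without control replicate 2, whose cox1 value was -2.39, the cox1 difference was -1.21 with an adjusted p of 2.05e-04, the 1 family call that leaving out an array gave in this comparison. That array is the one with 262 intensities set to blank. The cox1 calls given below for its removal share the same remaining controls, so they are not independent.

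In the same comparison 1 of the 13 lists passed the set test: the 6 families of lignin and aromatic degradation lay higher than the other families under warming (camera with a preset correlation, adjusted p = 0.0102). The correlation estimated among the 6 families was 0.576, far above the preset 0.01, so the preset test passes too easily here. With the estimated correlation the camera adjusted p was 0.976. The fry test, which asks whether the members move one way on balance and does not compare them with other families, gave an adjusted p of 0.982. None of the 6 members passed on its own or when adjusted over the list alone (smallest adjusted p = 0.352). Their differences were 0.34 ± 0.24 for ligninase, 0.28 ± 0.16 for vdh (vanillin dehydrogenase), 0.16 ± 0.11 for glx (glyoxal oxidase), 0.11 ± 0.12 for mnp (manganese peroxidase), 0.11 ± 0.13 for phenol oxidase and 0.10 ± 0.12 for vanA (vanillate demethylase). All 6 were above 0 after quantile, 75th percentile and total-signal scaling and below 0 without scaling, and the list did not pass with total-signal scaling (adjusted p = 0.215). The list was not called without control replicate 1 (adjusted p = 0.0617), control replicate 3 (0.0513) or warming replicate 3 (0.0511). The other 12 lists did not pass. Their median differences were 0.00 for denitrification, -0.08 for nitrate and nitrite reduction to ammonium, 0.03 for carbon fixation, 0.01 for starch, 0.01 for cellulose and hemicellulose (of its 9 families, cdh is annotated to terpenes), 0.07 for chitin and 0.01 for pectin degradation, 0.06 for phosphorus cycling, 0.04 for sulfate and sulfite reduction, 0.00 for sulfur oxidation, 0.03 for metal resistance and 0.04 for cyanobacteria and photosynthesis (adjusted p from 0.720 to 0.945). At probe level none of 28962 probes passed (1443, or 4.98%, had an unadjusted p under 0.05). Leaving out arrays gave 2 calls without control replicate 3 and 2 without replicate 1 of the combined treatment.

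**Figure D2:**
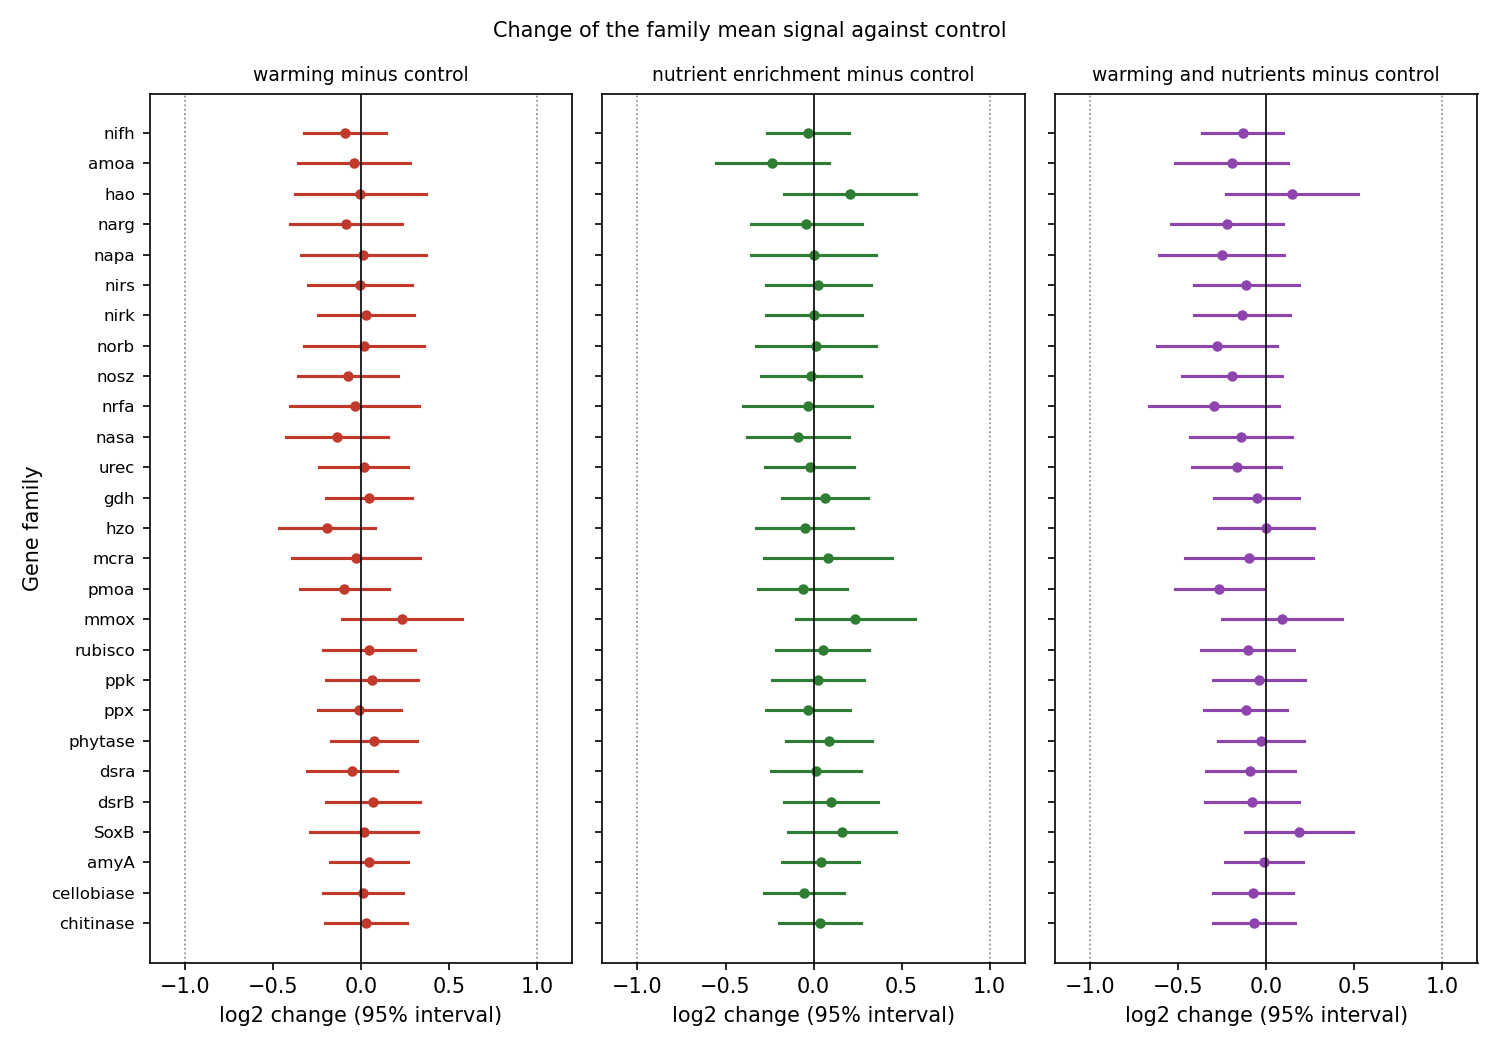
Change in the mean signal of 27 core gene families (y axis) against control, in log2 units (x axis), for warming, nutrient enrichment and both; points are limma estimates and bars 95% intervals, with dotted lines at a 2-fold change. Every interval lies inside the 2-fold lines; signs of these small changes depend on the scaling between arrays.

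For nutrient enrichment at ambient temperature, no family passed either (9 with an unadjusted p under 0.05 in limma, smallest adjusted p = 1.00), and 279 of 304 intervals excluded a 2-fold change. With quantile scaling the core families lay between -0.23 and 0.24. The lowest was amoA at -0.70 ± 0.26 (SD) in the enriched and -0.47 ± 0.18 in the control mesocosms, a difference of -0.23 ± 0.15 (SE), and the highest was mmoX at 0.24 ± 0.16. Of the 27 core families, 16 lay above 0 with quantile, 24 with 75th percentile and 26 with total-signal scaling. All 27 lay below 0 without scaling (-0.58 to -0.12), where array brightness enters. Differences were 0.21 ± 0.18 for hao (hydroxylamine oxidoreductase), 0.16 ± 0.14 for soxB of sulfur oxidation, -0.04 ± 0.15 for narG, -0.02 ± 0.13 for nosZ, -0.02 ± 0.12 for ureC (urease), 0.03 ± 0.12 for ppk and 0.09 ± 0.11 for phytase, which releases phosphate from phytic acid. The 5 smallest p values, none passing, were those of Viridiplantae cox1 (-0.68 ± 0.23), the msmABCD genes (0.80 ± 0.31), amyX of starch degradation (-0.65 ± 0.25), beta-agarase (0.27 ± 0.11) and the actin gene of ciliates (0.66 ± 0.28). The beta-agarase difference turned negative only without scaling, where array brightness enters. No list passed (smallest adjusted p = 0.888); the 5 carboxysome families tested as the cyanobacteria and photosynthesis list had a median difference of 0.13. No probe passed (1058, or 3.65%, had an unadjusted p under 0.05), while 3 passed without nutrient enrichment replicate 2 and 2 without control replicate 3. Without control replicate 2 the cox1 family passed at -0.99 (adjusted p = 0.00218).

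Under warming and nutrients together, no core family of denitrification or nitrate reduction passed the limma test. With quantile scaling the differences were -0.22 ± 0.15 for narG, -0.25 ± 0.17 for napA, -0.11 ± 0.14 for nirS, -0.14 ± 0.13 for nirK, -0.28 ± 0.16 for norB, -0.20 ± 0.13 for nosZ and -0.30 ± 0.17 for nrfA (nitrite reduction to ammonium). The denitrification list had 6 of 6 members below 0 with a median of -0.21 and did not pass (adjusted p = 0.283; adjusted p = 0.9498 with an estimated correlation). The lowest unadjusted p of a core family was that of pmoA, -1.88 ± 0.042 (SD) against -1.62 ± 0.25 in the controls, a difference of -0.27 ± 0.12 (SE, limma adjusted p = 0.687). In all, 24 of 27 core families lay below 0 with quantile scaling, 10 with 75th percentile scaling, 8 with total-signal scaling and 24 without scaling. The arrays of this group also had the fewest probes with a value on average, and the median over all 304 families was -0.09. This median turned positive with 75th percentile (0.04) and total-signal scaling (0.06), with blanks left missing (0.03) and over only the probes with a value on all 16 arrays (0.02). It was 9.50e-04 without control replicate 1, -0.03 and -0.14 without replicates 1 and 4 of the combined treatment and -0.16 without control replicate 3. No family passed (19 with an unadjusted p under 0.05, smallest adjusted p = 0.501), and 275 intervals excluded a 2-fold change. The 5 smallest p values belonged to nicdehydr (annotated to heterocyclic aromatics, 0.71 ± 0.21), heparinase (-0.55 ± 0.17), the jakobid elongation factor (1.10 ± 0.35), Viridiplantae cox1 (-0.69 ± 0.23) and adhC (-1.43 ± 0.48). No probe passed, although 2349 (8.11%) had an unadjusted p under 0.05. Leaving out replicate 2 of the combined treatment gave 7 probes and leaving out control replicate 3 gave 2. Without control replicate 2 the cox1 family passed at -0.99 (adjusted p = 0.00213).

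Averaged over both nutrient levels, 1 of 28962 probes was higher in the warmed mesocosms (1930, or 6.66%, had an unadjusted p under 0.05). It is a probe for fthfs, formyltetrahydrofolate synthetase of the reductive acetyl-CoA pathway of carbon fixation, from an uncultured bacterium (probe 300390440). It had a value on all 16 arrays. Its normalised log2 signal was 2.71 ± 2.11 (SD, n = 4) in the controls, 5.74 ± 0.40 under warming, -0.80 ± 1.26 under enrichment and 5.87 ± 0.80 under both. The averaged difference was 4.84 ± 0.60 (SE) log2 units, a 28.7-fold higher signal (limma adjusted p = 0.0170). The 8 warmed mesocosms lay between 4.69 and 6.40 and the 8 unwarmed between -1.93 and 5.61, with control replicate 4 as the highest of the unwarmed. The call was lost, with the difference at 4.76 to 4.92, when any of 9 arrays was left out (all 4 of warming, replicates 2 and 4 of the combined treatment, replicates 1 and 3 of enrichment, or control replicate 2; adjusted p up to 0.0759). It was also lost with 75th percentile and total-signal scaling (adjusted p = 0.149 and 0.132), without the filter on dim probes (0.121) and without the 4 arrays with the fewest values (0.334). With groups taken by matching the column headings to the description codes, the difference was 0.93 (adjusted p = 0.902). The mean of all 434 fthfs probes differed by -0.073 ± 0.089. Besides the fthfs probe, 1 more passed without control replicate 3 (ara, -2.71), without enrichment replicate 2 (PRI, -2.18) and without replicate 1 of the combined treatment (tktA, 3.11).

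**Figure D3:**
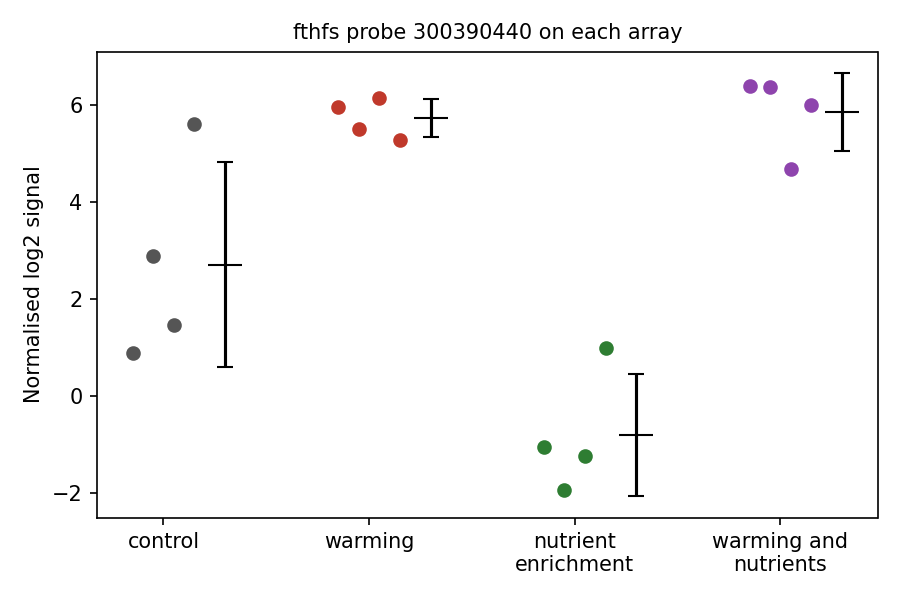
Normalised log2 signal (y axis) of the fthfs probe on each of the 16 arrays by treatment group (x axis); coloured points are mesocosms and black bars the mean ± SD of 4. The 8 warmed mesocosms lie between 4.69 and 6.40, and 1 control mesocosm lies in that range at 5.61.

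No family passed for warming averaged over both nutrient levels (8 with an unadjusted p under 0.05), and 298 of 304 intervals excluded a 2-fold change. Heparinase had the smallest p, at -0.45 ± 0.12 (limma adjusted p = 0.454), followed by nicdehydr (0.46 ± 0.15), Viridiplantae cox1 (-0.45 ± 0.16), the jakobid elongation factor (0.66 ± 0.25) and oorA of the reductive tricarboxylic acid cycle (0.41 ± 0.16), all with an adjusted p of 0.899. Core families lay between -0.15 for pmoA and 0.04 for mmoX with quantile scaling, where 25 lay below 0. With 75th percentile scaling 13 lay below 0, with total-signal scaling 12 and without scaling 26. The lignin list also passed here (camera with a preset correlation, adjusted p = 0.0318), in a comparison that includes the same warming and control arrays. With the estimated correlation of 0.576 the camera adjusted p was 0.9499. The list median was 0.08, against -0.05 over all 304 families, and no member passed alone. Ligninase was at 0.23 ± 0.17, vdh at 0.14 ± 0.11 and mnp at 0.13 ± 0.09. Near 0 lay phenol oxidase (0.03 ± 0.09), glx (0.02 ± 0.08) and vanA (0.02 ± 0.09). The list did not pass with total-signal scaling (camera adjusted p = 0.181) or with a replicate block (camera adjusted p = 0.0507). The list also did not pass when any of 8 arrays was left out: replicate 4 of the combined treatment (0.317), control replicate 3 (0.116), warming replicates 1, 3 and 4 (0.0566, 0.0854 and 0.0638) or enrichment replicates 1, 2 and 4 (0.0818, 0.0581 and 0.0535). In the combined treatment against control 3 of its 6 members lay above 0 (6 with 75th percentile or total-signal scaling, 2 without scaling) and the list did not pass (adjusted p = 0.283). In the interaction 5 of 6 lay below 0 (none without scaling), also without passing (adjusted p = 0.534). Leaving out replicate 4 of the combined treatment gave 2 family calls, oorA at 0.56 (adjusted p = 0.0294) and phtb at -0.56 (adjusted p = 0.0238), and leaving out control replicate 2 gave 1, cox1 at -0.61 (adjusted p = 0.00730).

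For enrichment averaged over both temperatures, neither a family (9 with an unadjusted p under 0.05 in limma, smallest adjusted p = 0.929) nor a probe passed (1233, or 4.26%, with an unadjusted p under 0.05), and 300 of 304 intervals excluded a 2-fold change. The families with the smallest p, none passing, were tcpA (annotated to herbicide-related compounds, -0.39 ± 0.13), fungal chitin deacetylase (-0.33 ± 0.12), amyX (-0.49 ± 0.18), ccl (-0.50 ± 0.20) and 4hbcd (0.44 ± 0.17), the last 2 from carbon fixation pathways. Among the core families amoA was lowest at -0.20 ± 0.11 and hao highest at 0.18 ± 0.12, with soxB at 0.17 ± 0.10. Of the core families 22 lay below 0 with quantile, 9 with 75th percentile, 6 with total-signal and 24 without scaling. No list passed (smallest adjusted p = 0.996). Between 1 and 2 probes passed without control replicate 3, enrichment replicate 2 or replicates 1 or 2 of the combined treatment.

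The interaction asks whether warming acts differently at the 2 nutrient levels. No family passed (6 with an unadjusted p under 0.05 in limma, smallest adjusted p = 0.960), no probe passed (1085, or 3.75%, with an unadjusted p under 0.05) and no list passed (smallest adjusted p = 0.534). The interval excluded a 2-fold difference for 237 of 304 families, fewer than for single effects because its error is larger (median SE 0.23 against 0.16). Viridiplantae cox1 (0.90 ± 0.33), PEP synthase (0.57 ± 0.26), axe (-0.39 ± 0.18), msmABCD (-0.96 ± 0.44) and cdo (-0.83 ± 0.39) had the smallest p values, and the axe value turned positive without scaling. With quantile scaling core families lay between -0.38 ± 0.23 for mmoX and 0.24 ± 0.18 for hzo of anammox, with 23 of 27 below 0; 22 were below 0 with 75th percentile and 26 with total-signal scaling, and none without scaling (0.21 to 0.81). The cox1 interaction passed without control replicate 2 (1.21, adjusted p = 0.00757), and 1 probe passed without control replicate 3 and 2 without enrichment replicate 2.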

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

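Of 204 groups of 4 values examined, 11 had 1 mesocosm far from the other 3 by Dixon's criterion. Chance gives about 1 in 20, or 10.2 groups, so the number itself is no pattern. The ara probe was named after its values were seen.

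The Shannon index of warming replicate 2 was 8.56, below the other warming mesocosms at 8.66 to 8.68, and this array is among the 4 with the fewest values. For Viridiplantae cox1, control replicate 2 was at -2.39 against -1.28 to -1.06, and warming replicate 2 at -2.14 against -2.46 to -2.43. The cmuA family was at -0.33 in replicate 2 of the combined treatment against -0.96 or lower in the others. Phytase was at -1.46 in replicate 1 of that group against -1.11 to -1.05. Beta-agarase was at -1.09 in enrichment replicate 1 against -1.17 to -1.16. The oorA family was at -1.54 in enrichment replicate 4 against -1.85 to -1.81, and at -2.11 in replicate 4 of the combined treatment against -0.99 to -0.89. The ccl family was at -1.50 in replicate 3 of the combined treatment against -2.04 to -1.98. The ara probe was at -2.62 in warming replicate 4 and at -2.06 in replicate 4 of the combined treatment, where the other 3 arrays of each group were at the floor of -3.19, so these 2 values stand apart only by the floor set for blanks.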

How the results depend on the processing

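Alternatives for blanks, off-scale values, column headings, few-value arrays and the covariate, and leaving out arrays for the gene lists, were chosen after the data were seen. The counts of changed families stayed at 0 in every comparison under all alternatives other than leaving out 1 array, and no share of community composition and no difference in detected probes or Shannon index crossed its threshold. Of 6800 values of named families under other settings, 6145 moved by less than their standard error, 649 moved by more without passing and 6 passed. The fthfs probe kept its call in 12 of 17 alternatives. It was lost at 4.99 with 75th percentile scaling, 4.98 with total signal, 4.84 without the filter and 4.83 without the 4 arrays with the fewest values, with 0 probes called for averaged warming in each. Without the filter its limma standard error rose from 0.601 to 0.626 and its unadjusted p from 5.88e-07 to 2.92e-06, over 41370 instead of 28962 probes; for the scalings the cause was not tested. Grouped by matching headings to description codes, it was at 0.93 with 0 probes and 0 families called in all 6 comparisons, so this call rests on the treatment labels. Probe calls for warming against control became 1 with array weights, with only the groups compared, without the 4 arrays and with the number of values as a covariate. For enrichment against control they became 1 with array weights, blanks left missing, without the 4 arrays or with the covariate, and 3 without scaling. For both treatments against control they became 1 with 75th percentile scaling, 6 without scaling and 2 without the 4 arrays. For averaged enrichment they became 1 without scaling or without the 4 arrays, and for the interaction 2 without scaling; the cause was not tested. List calls went from 2 to 0 with an estimated correlation or total signal, and to 1 with the replicate block (adjusted p = 0.0507 for the lignin list in averaged warming). The fry test, which does not compare a list with other families, called 0 lists. With 1 array left out, family calls ranged from 0 to 1 for each treatment against control and the interaction, from 0 to 2 for averaged warming and stayed at 0 for averaged enrichment. Probe calls ranged from 0 to 2 for warming, 0 to 3 for enrichment, 0 to 7 for both, and 0 to 2 for each averaged effect and the interaction; the fthfs difference ranged from 4.54 to 5.33 and list calls from 0 to 2. Median family changes shifted by over 0.1 between scalings: by 0.15, 0.18 and 0.15 for the treatments against control with total signal, by 0.12 for both treatments with the 75th percentile, and by -0.31, -0.37 and -0.12 without scaling; the interaction shifted by -0.17 with total signal and 0.57 without scaling. Over the 24 pairs of all groups, mesocosms of the same replicate number did not all deviate together (correlations -0.08 to 0.17, mean 0.03). The number was therefore not taken as a pairing. Within a nutrient level, the unwarmed and the warmed mesocosm of a number also share the letter in the column heading, whose meaning is not given. These pairs correlated at -0.04 to 0.09 for control and warming, with replicates 2 and 4 best with their own number. For enrichment and combined mesocosms they correlated at 0.07 to 0.16, each best with its own number. A pairing by letter is thus not excluded, and the regroupings of mesocosms did not keep these letters together. In limma with the heading letter as a random block, the fthfs probe was at 4.84 (adjusted p = 0.0130). The replicate block changed no family or probe count. Spots left blank limit the data: the share of kept probes at the floor was 6.61% to 42.0% per array. Normexp, a slide batch and detection by a signal score were not run, since the values needed were not given.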

Other observations

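The few-value test of the fthfs probe was chosen after its result was seen, and the sets and probes named here were chosen after the data were seen.

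For enrichment averaged over both temperatures, the smallest p among categories of the annotation was that of the one named Phylogenetic, and among phyla that of the diatoms (Bacillariophyta). The 14 families of the first lay higher (camera p = 0.00420) and did not pass after adjustment over 40 categories (adjusted p = 0.168; 0.990 with an estimated correlation). The 32 diatom probes lay higher (p = 0.0104) without passing over 21 phyla (adjusted p = 0.219; 0.306 with an estimated correlation). For warming averaged over both nutrient levels, the 203 probes of Deinococcus-Thermus came closest to passing among phyla (limma's camera, adjusted p = 0.356). No phylum or category passed in any of the 6 comparisons.

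The fthfs probe was 4.84 log2 units higher in warmed mesocosms. Among 100 groupings of warming within nutrient levels, the real one among them, 11 gave at least 1 probe call (highest other 3). Chance therefore cannot be excluded for a count of 1. These groupings did not keep mesocosms of the same heading letter together. A change of the whole fthfs family is argued against by the family mean of -0.073 ± 0.089 (SE). Without the 4 arrays with the fewest values the difference was 4.83 ± 0.75 (SE), so its size does not rest on them. The probe had a value on all 16 arrays and its values were known when this check was chosen, so the check is weak. The limma adjusted p was then 0.334, with a larger standard error than the 0.60 of all arrays. The smallest adjusted p in that fit was 0.233 and belonged to another probe. Why the call was lost was not tested. A warming response of 1 population carrying this sequence, cross-hybridisation and chance may each account for the higher signal of the probe and stay open. The first 2 were not tested.

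In the combined treatment 8.11% of probes had an unadjusted p under 0.05, where 5% is the share without any effect. The share was 8.60% with the number of probes with a value as a covariate. That covariate is linear and the number was lowest on average in this group, so an effect of the number is not excluded. Chance cannot be excluded either. Of the 35 splits of the 8 mesocosms, the real one among them, 7 gave at least 2349 probes. The highest other split gave 3222. An effect of the combined treatment stays open.

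An ara probe (annotated to hemicellulose degradation, Bryantella formatexigens) and a nosZ probe (uncultured bacterium) set the controls apart from all 3 treated groups. With controls tested against the 12 treated mesocosms in limma, the ara probe was at -4.44 ± 0.53 (SE, adjusted p = 0.00371) and the nosZ probe at -2.70 ± 0.39 (adjusted p = 0.0247). The ara probe had a value on all 4 control arrays (-1.28 to 3.12) and on 4 of 12 treated arrays; the nosZ probe was between -0.52 and 0.94 in the controls and between the floor and -1.31 elsewhere. Of 100 choices of 4 of the 16 mesocosms, the real one among them, 14 gave at least 2 calls. The highest other count was 25, so chance may account for the number of such probes.

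Splits say nothing about a comparison with 0 calls, since each of the 35 splits (treatment against control) or 100 regroupings (averaged effects and interaction) gives at least 0. For families, whose real count was 0 in all 6 comparisons, the highest other counts were 1 for warming, 1 for enrichment, 7 for both together, 72 for averaged warming, 1 for averaged enrichment and 10 for the interaction. For probes, in the 5 comparisons with a real count of 0, they were 2, 1 and 3 for the treatments against control, 3 for averaged enrichment and 7 for the interaction. The regrouping with 72 families may reflect a structure of the samples or families that vary together; neither was tested. For the gene lists, 8 of 100 groupings, the real one among them, gave at least 2 list calls (highest other 2), so chance cannot be excluded for them. Counts with an array left out or under other settings were not tested with splits.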
